A study of Homo sapiens with 4 samples.

How the data were processed

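Poly(A) RNA of RPMI-8226 cells transduced with lentivirus was made into an input library and an anti-m6A immunoprecipitated library for each of shNC and shALKBH5, per the labels' protocols. This gives 4 libraries, 1 per kind and condition. The submitters' processing notes name fastp 0.19.11, BWA 0.7.12, HOMER 4.9.1 and the build hg38, with no role or order, and the peak caller and its settings are not given in the sources used here. The authors deposited 1 peak list per condition, each made from 1 IP and 1 input library, with nothing pooled as far as the labels say. Per the file headers, each peak has a chromosome, a start, an end, a strand, blocks that follow splicing, an Ensembl gene and symbol, and a fold enrichment, which is the ratio of IP over input within the peak as the authors give it. The normalization between IP and input is not given in the sources used here. The column named score in the authors' tables holds the p-value of the peak, since it equals 10 to the power of the log10 p column within rounding. The authors' log10 p and log10 FDR columns were read as scores with no fixed range, because they pass -100. The largest FDR in either list was 0.0479, which lies under 0.05, and the lowest folds were 1.12 for shNC and 1.11 for shALKBH5. In the FDR column, 1079 shNC and 1109 shALKBH5 cells held a spreadsheet error in place of a number, as did 2 and 1 cells of the log10 p column, and these were ranked as the strongest values.

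No table holds read counts, so the depth of each library is unknown and the only precision that can be given is the counting error of peak numbers. Intervals are exact (Clopper-Pearson) 95% binomial intervals over peaks, which are not independent replicates. The comparison of shALKBH5 with shNC has 1 list per condition and no test between conditions. A peak was shared when its blocks had at least 1 base in common with blocks of a peak of the other list, strand ignored, found with bedtools 2.31.1. The tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. Each fixed gene list was set against 10000 random lists with the same numbers of genes per class of peaks summed over both lists, and its percentile describes these libraries only. The same comparison for peaks without a partner was added later. In both, the matching sum counts peaks of 1 list alone too. A gene with a sum of 1 can only stand in 1 list. The percentiles therefore compare genes of similar sums and cannot show whether a list holds many or few list-only genes or peaks. On simulated data, all 2000 planted peaks were given the right partner call (100%). All 1000 peaks planted near gene starts were placed at the right distance (100%), and a planted list of 40 genes reached percentile 100. The simulated sums were drawn apart from the list a gene stood in. That check therefore could not show the limit of the percentiles given above.

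Gene positions came from the RefSeq annotation of GRCh38.p14, matched to the authors' symbols or to a unique older symbol on the same chromosome, with the gene span overlapping the peak. This placed 19850 shNC peaks (88.4%) and 21723 shALKBH5 peaks (88.2%). A peak counted as lying at the gene start when its 5' edge was upstream of the RefSeq start or less than 500 bp downstream of it, and at the gene end when its 3' edge was less than 1000 bp from the end and it was not at the start. RefSeq gives 1 span per gene here, so an alternative start inside the gene was not seen. Of all peaks, 17.0% in the shNC list and 16.9% in the shALKBH5 list shared a base with another peak of their own list. Whether the libraries keep strand is not given in the sources used here, so peaks of overlapping or antisense genes cannot be told apart.

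The gene lists, the rule for named genes, the overlap and gene comparisons and the alternatives listed in this paragraph were chosen before the data were examined. The gene-start result with the alternatives made for it alone, the percentiles of peaks and most tests of explanations were chosen afterwards. The rule named ALKBH5 and TRAF1, the 10 genes per list with the highest fold among genes with no peak in the other list and no peak of it within 200 bp, the 10 shared peaks with the best lower rank by fold, and up to 4 members of each gene list with the highest folds. Pseudogenes, unnamed loci and immunoglobulin genes were left out of the fold rankings. Other genes are named because a count of few members needed it or because they were chosen after their values were seen, as with the start peaks and the mitochondrial peaks. Alternatives were a stricter fold, at least 2 times the lowest fold of the list, reciprocal overlap of 50%, a window of 200 bp, the same strand, merging of peaks within 100 bp, lists of equal length by p, and genes taken from RefSeq spans.

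Some planned results were not computed. A genome sequence was not used here, so shares of peaks with an m6A consensus motif and random placement of peaks in exons were not analysed. Exons, introns and untranslated regions were not analysed here either, so the planned share by transcript part was replaced, after the data were seen, by the position along the RefSeq span. The planned ratio of IP over input tags needs tag counts and was not computed. Some members of the gene lists are counted but their single results are not reported here.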

Results

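RPMI-8226, an established human multiple myeloma cell line, was profiled by m6A-seq, in which poly(A) RNA is enriched with an antibody against N6-methyladenosine (m6A) and sequenced beside the RNA before enrichment (the input). Cells carried either a short hairpin RNA against ALKBH5, an RNA demethylase that removes m6A, or the hairpin named shNC, and they are called shALKBH5 and shNC here. There were 4 libraries, 1 immunoprecipitated (IP) and 1 input library per condition, so no value had a replicate and no p-value between conditions was computed. The shNC list held 22448 peaks in 11318 genes and covered 7.50 Mb, and the shALKBH5 list held 24626 peaks in 12088 genes and covered 7.89 Mb. The median peak was 270 bases long in the shNC list and 269 bases in the shALKBH5 list. AHNAK, which encodes a very large scaffold protein, had the most peaks in both, with 18 in the shNC list and 19 in the shALKBH5 list. Sequencing depth is unknown, since the tables hold no read counts, and all intervals are exact 95% binomial intervals that cover counting error only. Peak folds of IP over input and peak p-values are the authors' own, and they describe or rank peaks within 1 list.

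The first question was what the lists showed at the targeted gene and at TRAF1, an adaptor of tumour necrosis factor receptor signalling that was chosen from knowledge of the study. ALKBH5 (ENSG00000091542, chromosome 17, RefSeq span 18183828 to 18209954 on hg38) had 3 peaks in each list, and each overlapped a peak of the other list. In the authors' deposited table for shNC, the ALKBH5 peak at the gene start, with 358 bases between 18183257 and 18184587, had a fold of 5.98, and the peaks toward the gene end had folds of 1.35 and 1.99. In the authors' deposited table for shALKBH5, the corresponding ALKBH5 peaks had folds of 5.71, 1.61 and 1.57. In the same order, their log10 p values were -599, -8.27 and -42.5 for shNC and -237, -9.42 and -9.93 for shALKBH5. The folds are ratios within a condition and hold no ALKBH5 expression level, so the knockdown itself was not checked here. TRAF1 (ENSG00000056558, chromosome 9, RefSeq span 120902393 to 120929171, minus strand) had 5 peaks in the shNC list and 6 in the shALKBH5 list. The TRAF1 peak without an shNC partner lay near the gene end, at 120902513 to 120902633, with a fold of 3.98 and a log10 p of -2.82 in the authors' deposited table. The strongest TRAF1 peak by p lay in the same place in both lists, at 120904462 to 120905062 with a fold of 12.4 for shNC and at 120904402 to 120905092 with a fold of 24.2 for shALKBH5. Near the TRAF1 gene start, a single peak ended at 120928709 in both lists, with a fold of 21 for shNC and 4.32 for shALKBH5 in the authors' deposited tables. Its log10 p was -10.6 for shNC and -5.27 for shALKBH5. The remaining shared TRAF1 peaks, toward the gene end, had folds of 16.9, 3.48 and 3.77 for shNC and 7.72, 11.8 and 4.88 for shALKBH5. Their log10 p values were -8.88, -7.45 and -8.38 for shNC and -20.7, -20.2 and -17.3 for shALKBH5.

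**Figure D1:**
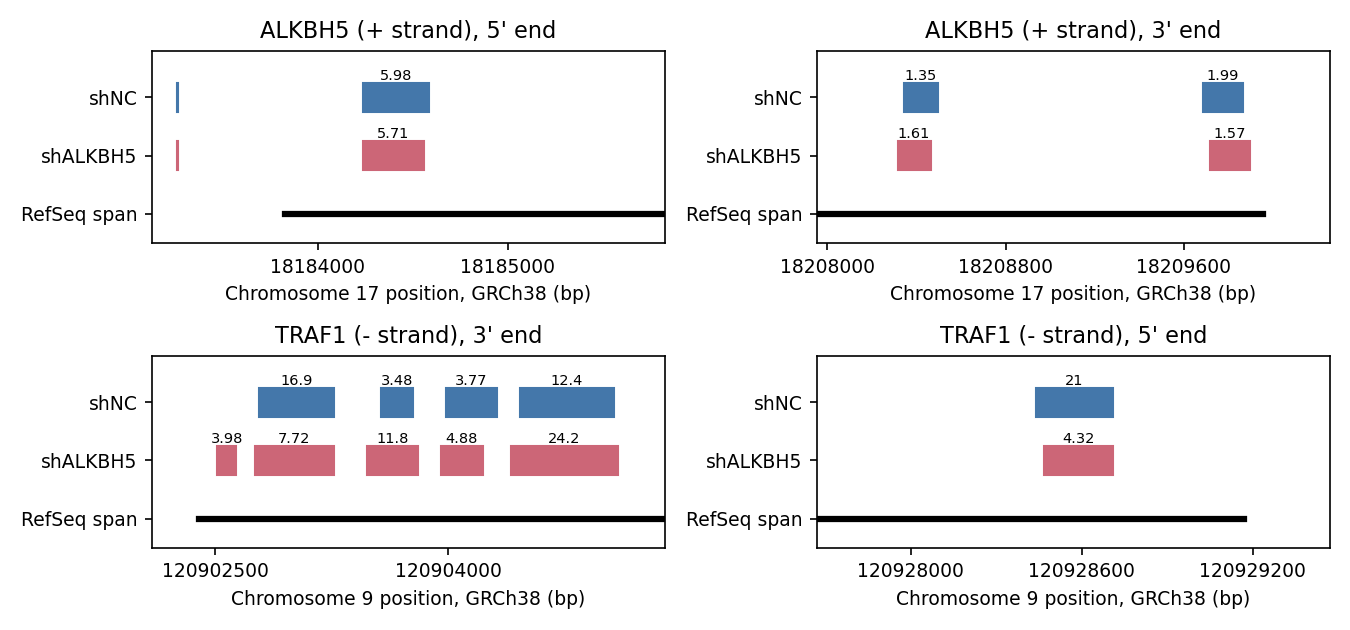
Peaks of ALKBH5 and TRAF1 at both ends of each gene, as blocks on the genome position (bp, GRCh38), with the authors' fold of IP over input above each peak and the RefSeq gene span as a black line. The spliced ALKBH5 peak at the gene start is drawn as 2 blocks, and the TRAF1 block with a fold of 3.98 in the shALKBH5 list has no shNC block above it.

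The next comparison asked which RNAs carried listed peaks with and without the hairpin against ALKBH5. Most genes appeared in both lists: 10614 of the 12792 genes with any peak, or 83.0%. Another 1474 genes had peaks only in the shALKBH5 list and 704 only in the shNC list. Among the genes of the shALKBH5 list alone, the highest fold belonged to PLAU, which encodes urokinase plasminogen activator, with 48.9 at chromosome 10, 73916574 to 73916812. XPNPEP3, a mitochondrial aminopeptidase, had 45.2, and the phosphatase gene DUSP23 had 36.2. C10orf55, whose peak shares bases with that of PLAU on the opposite strand, had 31.7, and the strand of the reads is not stated, so these neighbours cannot be separated. STON2 and SLC40A1, the iron exporter ferroportin, both had 30.8, and MPEG1 and the polarity gene LLGL2 both had 29.9. PLCH2, a phospholipase C gene, followed with 29 and the RNA-binding protein gene KHDRBS3 with 26.2, all in the authors' deposited table. The log10 p of these 10 peaks ran from -7.74 at PLCH2 to -13.7 at PLAU.

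Among genes of the shNC list alone, FAM214B had the highest fold, with 33 at chromosome 9, 35107735 to 35107945, followed by SLC2A4, an insulin-responsive glucose transporter, with 30.3. The authors' deposited table gave 26.8 for GPD1, a glycerol-3-phosphate dehydrogenase, 25.9 for the ubiquitin ligase UBR4, and 25 for both the phosphatase CDC14A and GAS2. MCIDAS, a regulator of multiciliated cells, had 24.1, TSTD1 had 22.3, and STAMBPL1 and NT5C1B both had 21.4. The log10 p of these 10 shNC peaks ran from -5.55 at NT5C1B to -8.98 at FAM214B. The peaks that ranked highest in both lists belonged to SYNCRIP, an RNA-binding protein gene, with folds of 93.7 for shNC and 124 for shALKBH5, and to MAP2K7, a kinase upstream of JNK, with 90.1 and 109. RGS12, THBS2, RIMS2, G6PC3, ZNF443, TATDN2, ZNF429 and KIAA1211 followed, with folds from 59.8 to 82.1 for shNC and from 66.1 to 87.8 for shALKBH5 in the authors' deposited tables. Of the list-only peaks with a fold of 15 or more, 81.2% (78.5 to 83.6%) had the commonest p for their fold, against 33.8% (32.7 to 34.8%) of peaks with a partner. Among those with a log10 p of -10 or weaker, the shares were 82.7% (80.1 to 85.1%) and 65.1% (63.0 to 67.1%).

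At the level of peaks, 87.4% of the shNC list (87.0 to 87.8%, 19619 of 22448) shared at least 1 base with an shALKBH5 peak, and 80.2% of the shALKBH5 list (79.7 to 80.7%, 19743 of 24626) shared one with an shNC peak. That left 2829 shNC peaks and 4883 shALKBH5 peaks without a partner. Peaks without a partner were mostly weak by the authors' p, with a median log10 p of -4.21 for shNC and -4.32 for shALKBH5, against -21.3 and -23.5 for peaks with a partner. In the quartile of weakest p, 38.7% of shNC peaks and 54.7% of shALKBH5 peaks had no partner, and in the strongest quartile 0.0713% and 0.0975% had none. In the stronger 50% of each list, the share without a partner was 0.454% for shNC (0.338 to 0.597%) and 1.53% for shALKBH5 (1.32 to 1.76%). When the shALKBH5 list was shortened by p to the length of the shNC list, genes in 1 list alone numbered 940 for shNC and 981 for shALKBH5. Equal numbers of peaks nearly force equal numbers of such genes, so neither pair shows how far the conditions differ in genes. Of the genes in 1 list alone, 93.9% for shNC and 87.9% for shALKBH5 had a single peak.

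**Figure D2:**
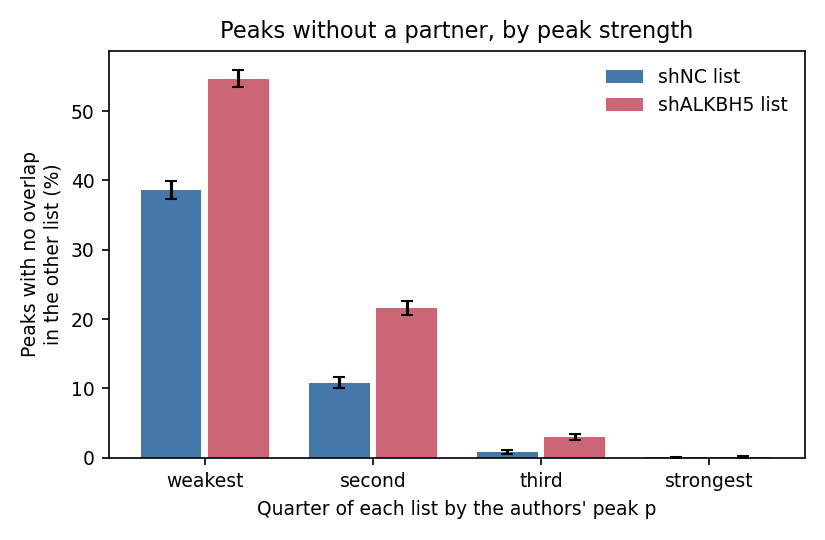
Share of peaks with no overlapping peak in the other list (%), by quartile of the authors' peak p within each list, for shNC (blue) and shALKBH5 (red), with exact 95% intervals for counting error. The share falls from 38.7% and 54.7% in the weakest quartile to under 1% in the strongest.

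Peaks listed only with shALKBH5 lay at gene starts more often than peaks of any other class, a result chosen after the data were seen. Leaving out pseudogenes and unnamed loci, PSMB4, a proteasome subunit gene, had the strongest such peak by p, at chromosome 1, 151399534 to 151399714, with a fold of 3.15 and a log10 p of -184 in the authors' deposited table. RPS2, a ribosomal protein gene whose retrocopies can share its reads, had a log10 p of -103, and IRAK1, a kinase of Toll-like receptor signalling, had a fold of 4.56 and a log10 p of -76.3 at chromosome X, 154019711 to 154019950. KIAA2013, PRELID1, KHSRP, TRAPPC4, FAM89B, TMEM123, TRIM28, BST2 and TXN completed the 12 strongest, with folds from 1.72 to 9.77. The cell cycle transcription factor gene E2F2 also had a start peak only in the shALKBH5 list, with a fold of 12.6 and a log10 p of -35, as did JUND, with a fold of 2.95 and a log10 p of -23.9. The strongest start peak listed only with shNC was at RPAP3, with a fold of 3.66 and a log10 p of -18.6 in the authors' deposited table, followed by TIGD5 with 4.24 and -16.6.

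Of 4158 shALKBH5-only peaks placed on a RefSeq gene, 1127 (27.1%, 25.8 to 28.5%) began upstream of or within 500 bp of the gene start. The share was 12.7% for shNC-only peaks (11.4 to 14.1%, 307 of 2422) and 11.5% for shALKBH5 peaks with a partner (2014 of 17565). Over all placed peaks, the lists differed less, with 11.4% for shNC (2267 of 19850) and 14.5% for shALKBH5 (3141 of 21723). The 1127 peaks lay in 1106 genes, and 773 of them were in genes that also had peaks in the shNC list. Their edge lay a median of 11 bp from the gene start, against 80 bp for the 307 shNC-only peaks. Among peaks with a log10 p below -10, the share at gene starts was 44.9% for shALKBH5-only peaks (40.1 to 49.7%, 196 of 437) and 8.11% for shNC-only peaks (4.26 to 13.7%, 12 of 148). With the shALKBH5 list shortened to the length of the shNC list, the shares over all list-only peaks were 30.2% and 13.3%. Peaks within 1000 bp of the gene end made up 16.9% of shALKBH5-only peaks (15.8 to 18.1%), 21.0% of shNC-only peaks (19.4 to 22.7%) and 23.3% of shALKBH5 peaks with a partner. With 1 IP and 1 input library per condition, this difference is one between 2 pairs of libraries. Nothing measures how far replicate cultures would differ.

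**Figure D3:**
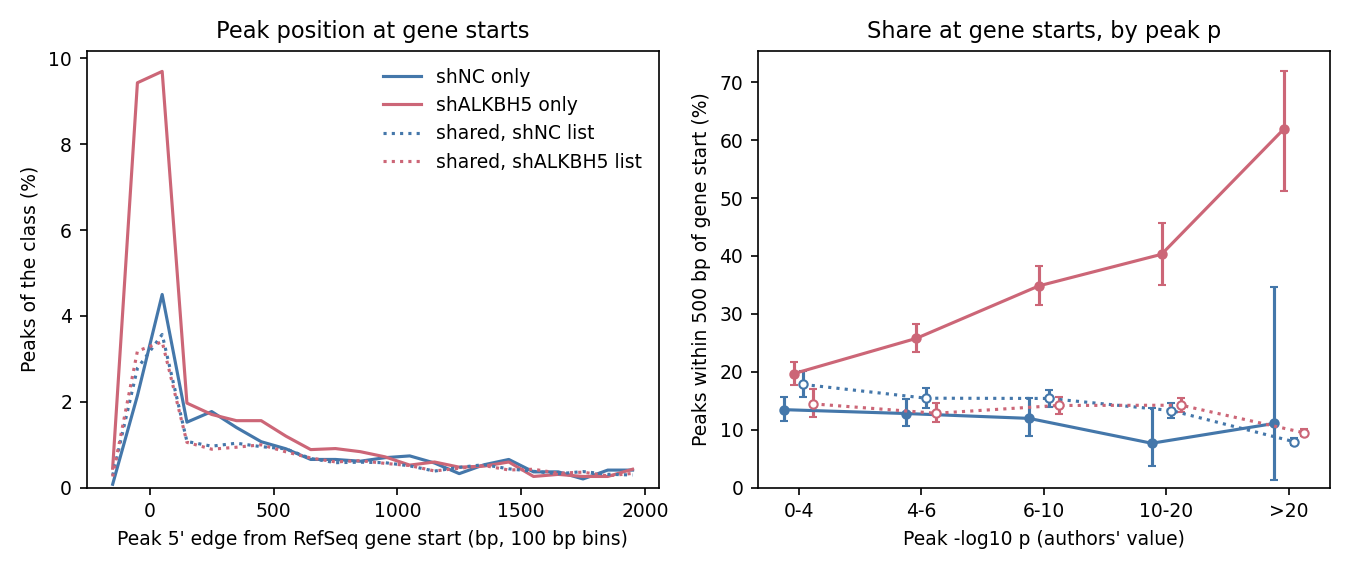
Left, share of each class of peaks (%) by the distance of the peak's 5' edge from the RefSeq gene start, in bins of 100 bp. Right, share of peaks (%) upstream of or within 500 bp of the gene start by band of the authors' -log10 p, with exact 95% intervals for counting error, where shALKBH5-only peaks rise from 19.7% to 62.0%, and shNC-only peaks stay between 7.69% and 13.5%, with 18 peaks in their strongest band.

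The 13 fixed gene lists held 367 distinct genes, of which 234 had peaks in both lists, 9 only in the shNC list, 20 only in the shALKBH5 list and 104 in neither. In MAPK signalling, a set of kinase cascades, 40 of 45 genes had a peak, 38 of them in both lists and 2 only in the shALKBH5 list. Among the latter was FOS, which encodes a subunit of the transcription factor AP-1. Folds given in pairs for list genes are the highest of any peak of the gene in each list, and the pair can come from different peaks. The highest folds of MAPK genes in both lists belonged to MAP2K7, MAPK3 (9.81 for shNC and 71.5 for shALKBH5), RASA1 (67.8 and 12.4) and JUN (52.6 and 17.9). MAPK genes had 6 peaks without a partner in the shNC list and 19 in the shALKBH5 list, of which 0 and 8 lay at gene starts. The 8 start peaks were at RPS6KA1, JUN, ELK4, FOSL2, MAPK14, MAP3K3, ELK1 and JUND, and their number stood at percentile 99.0 of 10000 random lists matched on peaks per gene, below the 99.99 of the housekeeping list. For start peaks listed only with shALKBH5, the other 11 lists stood between percentiles 7.27 and 88.5. In tumour necrosis factor receptor and NF-κB signalling, 34 of 37 genes had a peak and 31 had peaks in both lists, with RELB only in the shNC list and IKBKG and TRAF3 only in the shALKBH5 list. IKBKG has a near-identical pseudogene, so its peak is uncertain. The highest folds in this list were at TAB2 (9.81 for shNC and 38 for shALKBH5), TNFRSF13B (30.7 and 18.1), TNFRSF1A (27.2 and 10.4) and TRAF1 (21.0 and 24.2). Peaks without a partner in this list numbered 3 for shNC and 11 for shALKBH5, the latter in REL, RIPK1, NFKBIE, IKBKB, TRAF1, TRAF3, TRADD, NFKBIB, CD40, IKBKG and TAB3. Against matched random lists, the 3 stood at percentile 2.24 and the 11 at percentile 20.3. The sum used for matching counts these peaks too, so the percentiles cannot show whether either number was high in itself.

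Of the m6A writers, erasers and readers, 22 of 23 had a peak, and all 22 had peaks in both lists. The highest folds were at the reader YTHDF3 (127 for shNC and 20.4 for shALKBH5), RBM15 (26.2 and 13.5), WTAP (17.1 and 24.5) and IGF2BP3 (23.2 and 18.1). The YTHDF3 peak had the same borders in both lists, with a log10 p of -239 for shNC and -254 for shALKBH5. Its lower fold with shALKBH5 thus came without a weaker p. At YTHDF1, YTHDF2, IGF2BP2 and HNRNPC, a start peak of the shALKBH5 list had no shNC partner. Of the shNC-only peaks of these m6A genes, 0 lay at gene starts. YTHDF2 also had a start peak shared by both lists, at 28736950 to 28737219 for shNC. Its shALKBH5-only peak, at 28736711 to 28736800, lay within 200 bp of that peak. The 4 start peaks without an shNC partner stood at percentile 88.5 of matched random lists, and all 6 shALKBH5-only peaks of the list at 11.4. All 27 genes with a peak among 28 of the unfolded protein response and endoplasmic reticulum had peaks in both lists, led by SEL1L (42.8 and 23.8), PPP1R15A (22.3 and 7.69), EDEM1 (20.5 and 5.43) and SDF2L1 (19.2 and 10.2). Their peaks without a partner numbered 1 for shNC, at HSP90B1, and 11 for shALKBH5, with start peaks at ATF6, DNAJB11, DNAJB9 and SDF2L1. Matched random lists put the 1 at percentile 2.44, the 11 at 79.7 and these 4 start peaks at 88.5. All 32 chromatin regulators had peaks in both lists, with 13 shNC-only and 19 shALKBH5-only peaks (17 and 15 with lists of equal length), and the highest folds were at HDAC4 (94.6 and 22.6), KDM6B (21.6 and 78.4), EED (35.2 and 32.8) and CHD8 (15.9 and 31.3). All 23 apoptosis genes with a peak, of 29, had peaks in both lists, led by the caspase inhibitor CFLAR (73.6 and 9.95), BBC3 (15.7 and 39.8), BCL2 (30.9 and 34.1) and MDM2 (28.9 and 26.8), with 6 shNC-only and 5 shALKBH5-only peaks (4 and 8 among peaks with at least 2 times the lowest fold of their list). With peaks required to reach 2 times the lowest fold of their list, the shALKBH5 list alone held 1 gene of m6A, 2 of the unfolded protein response, 2 of chromatin and 1 of apoptosis.

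Of 32 plasma cell and myeloma genes, 23 had a peak, 22 of them in both lists, and CCND3, a D-type cyclin, had one only with shALKBH5. The lymphoid transcription factor genes IKZF3 (23.3 for shNC and 18.2 for shALKBH5) and IKZF1 (16.4 and 14.1), MYC (22.9 and 21.1) and PRDM1 (15.7 and 14.6) had the highest folds, and each list held 5 peaks without a partner in this group (2 for shNC and 8 for shALKBH5 with that fold limit, 6 and 4 with lists of equal length). In the cell cycle list, 18 of 27 genes with a peak had peaks in both lists, with AURKB, CDKN1A, RB1 and TOP2A only in the shNC list, and CCNB1, CCND3, CCNE1, CCNE2 and CDK2 only in the shALKBH5 list. These list-only cell cycle genes had best folds from 1.24 to 6.15. With peaks required to reach 2 times the lowest fold of their list, 3 genes of this group stood in each list alone. With lists of equal length, 5 stood in each list alone. Of 45 cytoplasmic ribosomal protein genes, 18 had a peak, 10 of them in both lists, with RPL19 and RPS15 only in the shNC list and RPL14, RPL24, RPL6, RPS2, RPS28 and RPS9 only in the shALKBH5 list. Of 20 housekeeping genes, 15 had a peak, 11 of them in both lists and 4 only in the shALKBH5 list, among them HPRT1, LDHA and SDHA, a number at percentile 99.1 of matched random lists, where the other 12 lists stood between 16.2 and 84.7. Housekeeping genes had 2 shNC-only and 9 shALKBH5-only peaks, 6 of the latter at gene starts (percentile 99.99), and with lists of equal length the 9 became 3. Reads of ribosomal protein and housekeeping genes can come from processed pseudogenes, so these members are uncertain. Markers of other cell types were mostly without peaks, which 2 of 18 T and NK cell genes (CD8A and CD8B), 3 of 16 myeloid genes (ITGAM, CD68 and C1QA) and 2 of 13 stromal genes (PDGFRB and CXCL12) had. The 26 percentiles of genes were planned, 52 percentiles of peaks were added after the data were seen, and none is adjusted for their number. The sum of peaks used for matching includes those of 1 list alone. The match thus fixed part of each number, and the percentiles hold only among genes of similar sums.

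**Figure D4:**
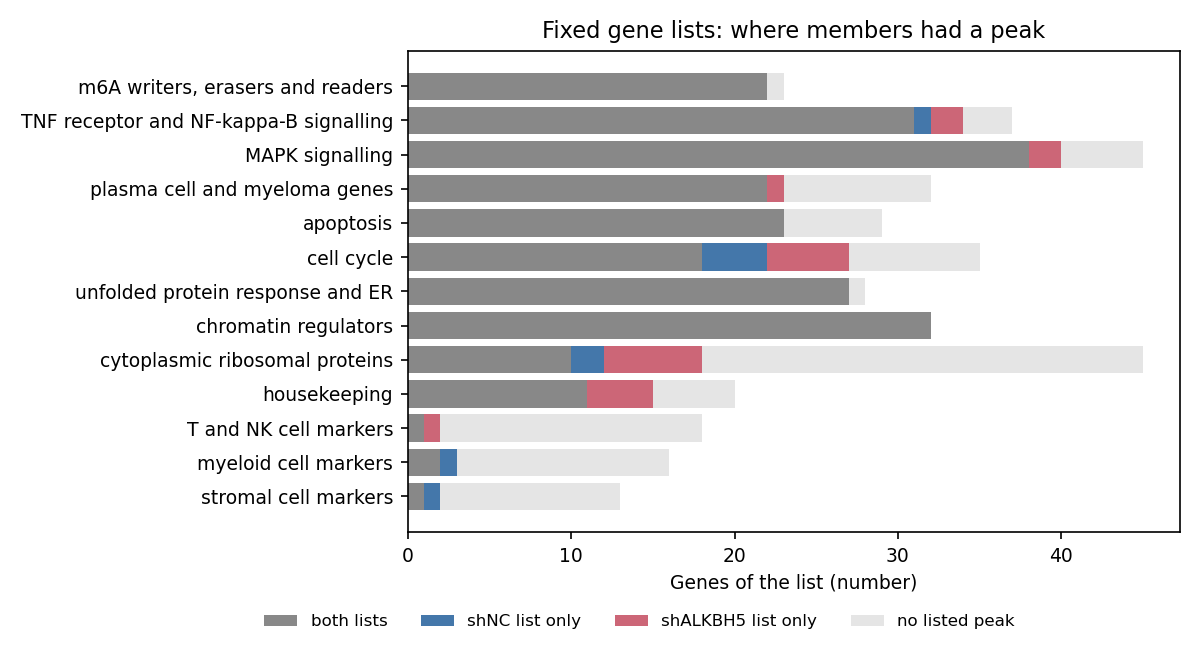
Number of genes of each fixed gene list with a peak in both lists (dark grey), only in the shNC list (blue), only in the shALKBH5 list (red) or in neither (light grey). Chromatin regulators had peaks in both lists at all 32 genes, and the cell cycle list held 4 genes only in the shNC list and 5 only in the shALKBH5 list.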

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

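Other distances from the gene start, the p limit and the neighbour limit were chosen after the data were seen. So were the restrictions to genes of both lists or of 1 list alone, and the removal of peaks that share bases within a list. The other alternatives were planned, but the gene-start result that some of them were applied to was not. No paired analysis was possible because each group holds 1 library. Of the main values under an alternative, 31 stayed within their 95% interval or within 1.5 times their count and 24 moved. The share of shNC and of shALKBH5 peaks with a partner was 77.8% and 70.9% with reciprocal overlap of 50%, 89.4% and 82.4% with peaks within 200 bp counted, 86.2% and 78.5% with the stricter fold in both lists, and 88.9% and 81.5% with the stricter fold only in the list looked at. With lists of equal length both shares were 84.9%, which equal numbers of peaks nearly force, and 981 genes stood in the shALKBH5 list alone. At gene starts, the shares of shNC-only, shALKBH5-only and shared peaks were 8.42%, 22.3% and 8.62% within 200 bp, 16.2%, 31.7% and 14.8% within 1000 bp, and 8.11%, 44.9% and 10.6% with a log10 p below -10. The shALKBH5-only share was 30.2% with lists of equal length and 28.5% with no other-list peak within 200 bp. The shared one was 10.7% without peaks that share bases within a list. In genes of both lists, the shNC-only and shALKBH5-only shares were 10.5% and 26.3%. In genes of 1 list alone they were 20.8% (17.4 to 24.5%) and 29.1% (26.6 to 31.8%), a smaller gap. Under each of these alternatives the shALKBH5-only share stayed above the shNC-only share. The causes of the other moves were not tested. For single gene lists, 86 of 104 counts stayed within 1.5 times and 18 did not, among them shALKBH5-only peaks of m6A genes (6 to 10), myeloma genes (5 to 8), apoptosis genes (5 to 8) and ribosomal protein genes (9 to 4) under the stricter fold. The order of shNC-only and shALKBH5-only peaks turned around for apoptosis genes under the stricter fold (6 and 5 to 4 and 8), and with lists of equal length for chromatin regulators (13 and 19 to 17 and 15) and cell cycle genes (7 and 8 to 9 and 8). For myeloma genes, equal numbers of 5 became 2 and 8 under the stricter fold and 6 and 4 at equal length. Exonic peaks, the motif, the transcript part and the tag ratio were not run, since sequence, exons and tag counts were not used here. Unknown depth limits every count of peaks in 1 list.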

Other observations

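The tests by peak p, by the number of libraries, by read totals and by repeated fold values, and the genes named here, were chosen after the results were seen; the tests of moved borders and of peaks away from gene starts were also chosen after the data were seen, but before their own values were computed.

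Transcripts of the mitochondrial genome had 15 peaks in the shNC list and 9 in the shALKBH5 list. All 9 overlapped an shNC peak, and 6 of the 15 shNC peaks had no partner. The strongest mitochondrial peak in both lists lay at MT-ATP8, a subunit gene of ATP synthase, at 8366 to 8572, with a fold of 6.63 for shNC and 3.71 for shALKBH5 in the authors' deposited tables. MT-ND1, MT-CYB and MT-ND6 had peaks only with shNC, among them 2 at MT-ND1 with folds of 3.19 and 1.79. Reads of these genes can also come from nuclear copies of mitochondrial DNA, so the gene of origin is uncertain.

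Leaving out pseudogenes and unnamed loci, the strongest nuclear shNC-only peak by p lay at HSP90B1, an endoplasmic reticulum chaperone gene, with a fold of 1.6 and a log10 p of -36.2 in the authors' deposited table. It was followed by peaks at SFTPA1, MLEC and YWHAG. Away from gene starts, the strongest shALKBH5-only peaks lay at DDX5, an RNA helicase gene, 529 bp from its start with a fold of 2.02 and a log10 p of -57.7, and at RPL14 with 1.58 and -54.7. Pseudogenes made up 5.49% of shNC-only peaks (133 of 2422) and 3.39% of shALKBH5-only peaks (141 of 4158) with a RefSeq gene. In a subset chosen after the data were seen, they made up 10.1% of shNC-only peaks with a log10 p below -10 (5.78 to 16.2%, 15 of 148) and 1.14% of such shALKBH5-only peaks (0.373 to 2.65%, 5 of 437). Their reads can come from the parent genes.

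The excess of shALKBH5-only peaks at gene starts was first weighed against weak peaks near the calling threshold. Among peaks with a log10 p below -10, the share was 44.9%, against 8.11% for shNC-only peaks. This argues against peaks weak in their own list as the whole account. Of the 1127 start peaks, however, 196 were that strong, and the median log10 p of the 1127 was -5.32. Most of the start peaks thus lie outside this comparison. Moved borders of peaks held by both lists are argued against too, since without any peak within 200 bp of the other list the shares were 28.5% and 12.9%. A difference between the single IP or input libraries that the knockdown did not cause cannot be told apart from the knockdown. Each condition has 1 IP and 1 input library. The knockdown of ALKBH5, the difference the design names, stays open as untested.

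More peaks were listed only with shALKBH5 than only with shNC. In the stronger 50% of each list, 1.53% of shALKBH5 peaks (188 of 12313) had no partner, against 0.454% of shNC peaks (51 of 11224). Peaks weak in their own list are therefore not the whole account. They still made up most of the peaks without a partner, which numbered 4883 for shALKBH5 and 2829 for shNC. A peak's p in its own list does not show how near the calling threshold the same place lay in the other. Nearness to the threshold there stays open. With lists of equal length, 84.9% of either list had a partner, which equal numbers of peaks nearly force. Peaks at gene starts, of which 93 against 7 lacked a partner in the stronger 50%, are not the whole of the excess either. Away from gene starts the numbers were 82 and 38, a ratio of 2.16 (1.45 to 3.26). Deeper sequencing of the shALKBH5 libraries could give the same picture and stays open, because 0 columns of the tables hold read counts or totals.

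High folds of peaks in 1 list, such as those of PLAU and FAM214B, may reflect an input at or near its lowest value. Of list-only peaks with a fold of 15 or more, 81.2% had the commonest p for their fold, against 33.8% of shared peaks in that range. With a log10 p of -10 or weaker the shares were 82.7% and 65.1%, so much of the gap goes with weak p rather than with being in 1 list. The 362 shNC-only peaks took 28 fold values and the 593 shALKBH5-only peaks 41, against medians of 143 and 185 in equal numbers of shared peaks drawn at random, but with weak p the numbers were 27 against 30 and 28 against 29. No biological account of the repeated values was tested.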
